A study of Arabidopsis thaliana with 25 samples.

How the data were processed

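Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 4 transcript elongation factors and transcribing RNA polymerase II (RNAPII) in Arabidopsis thaliana Col-0 seedlings. SPT5 is a subunit of the SPT4-SPT5 complex that travels with RNAPII, ELF7 is the plant PAF1 subunit of the PAF1 complex, and SSRP1 and SPT16 are the 2 subunits of the histone chaperone FACT. RNAPII was precipitated by its carboxy-terminal domain phosphorylated at serine 2 (S2P) or at serine 5 (S5P). The 25 samples comprised 4 ChIP libraries for each factor, 2 for each RNAPII form and 5 input libraries, 1 of them for each factor and 1 for RNAPII. Seedlings grew with 16 h of light, at 21 °C in the light and 18 °C in the dark. The labels' protocols also describe heat at 44 °C for 10 min under every sample, but no sample label says that a sample was heated, so no heated group was formed.

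The deposited files analysed here were 8 lists of peak summits, 1 for each factor with each RNAPII form. Per the submitters' processing notes, Trimmomatic 0.39, Bowtie2, SAMtools 1.16.1, deepTools and MACS3 were used with the TAIR10 genome; versions of the others and the MACS3 settings are not given in the sources used here. The summit score deposited by the authors is the −log10 of the MACS3 q-value, and the lowest score over all lists was 2.00, which corresponds to a q threshold of 0.01. Scores are the authors' own and were used to describe, rank or filter summits within a list. Each list holds calls with no column per library, so no value has a replicate error, no library could be left out, and sequencing depth is unknown. Intervals given for shares are exact Clopper-Pearson 95% intervals that cover counting error in a list only, and p-values concern these lists, since neither genes nor summits are replicates. Whether the libraries came from separate cultures is not given in the sources used here.

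The names of the lists set a factor over an RNAPII form. Within a factor, 1.75% to 54.8% of summits stood at the same base in both lists, against at most 0.857% for lists of different factors over the same form, and none of the summits at shared bases had equal scores. The factor libraries were therefore read as the treatment and the named RNAPII libraries as the control, a reading that the files themselves do not state. How the libraries of a factor or form were pooled is not stated either. A summit then marks a place where the factor exceeded what that RNAPII form showed there, not the factor's occupancy alone.

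Summit positions were counted from 1. Genes came from an NCBI RefSeq gene table of assembly TAIR10.1, from which no coordinate is printed. Its registration with the lists was checked by shifting: in the 7 lists other than SPT5 over S5P, whose summits lie at gene ends, 90.1% to 92.2% of summits per chromosome lay in protein-coding genes unshifted, against 75.9% to 79.0% after a shift of 500 bp, and the unshifted share exceeded the shares after these shifts in 25 of 25 segments of 5 Mb. This does not resolve smaller shifts: over all chromosomes the share in these 7 lists was 91.0% unshifted and 91.4% to 91.9% after shifts of 100 and 200 bp, and in all 8 lists 87.4% and 88.8% to 89.8%, with 77.7% to 77.8% after 500 bp. A second check, added after the data were seen, took the median signed distance of summits to left and to right gene ends within 500 bp, whose mean is moved by a shift and not by a place inside or outside genes. It was 2.5 bp for SPT5 over S5P (95% interval −1.5 to 7.01), and the only list whose interval excluded 0 was SPT16 over S5P, with 10.5 bp (1.5 to 17.5). The intervals were wider where fewer summits lay at gene ends, at −29.5 to 105 bp for SPT5 over S2P, −51.5 to 36 bp for ELF7 over S5P and −12 to 29.5 bp for ELF7 over S2P, so that these lists fix the register less closely by themselves. The table holds neither strand nor exons. The design had planned 5′ and 3′ classes, positions oriented from the 5′ end and intron numbers. In their place stand the distance to either gene end, a folded position from 0 at a gene end to 0.5 at the gene centre, and a test, chosen after the data were seen, of whether 2 summits lie on the same side of the gene centre. Whether a gene end is the start or the end of transcription, and whether a summit is exonic, was not analysed here. All 377 fixed gene identifiers matched the table, which holds 27444 protein-coding nuclear genes.

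Location was compared with 1000 random placements on the same chromosomes, with a window of 500 bp at gene ends and a two-sided empirical p. Folded positions used the strongest summit per gene in genes of at least 1000 bp. They were compared by two-sided permutation tests of medians, with intervals from 2000 bootstrap draws. These tests used 100000 permutations, or 10000 for differences between shifts and for most alternatives. Alternatives of differences between shifts, gene length and score correlations used 2000 permutations. Gene sets were compared by two-sided Fisher's exact tests over 28 pairs of lists. Summits within 250 bp of each other were counted against 1000 placements inside the same genes. Gene groups were 12 lists fixed by identifier plus cytosolic ribosomal proteins chosen by name, after 14 organellar names were removed; they were tested by Fisher's exact tests against all protein-coding genes and by 10000 random lists matched on 10 classes of gene length. Group members were compared with the other genes of a factor's lists by Fisher's exact tests, on how many genes of the S2P list were also in the S5P list and on how genes found in only 1 list divided; these replaced sign tests that expected an even split. Gene lengths were also compared with 1000 draws of genes in proportion to length. Scores were correlated across genes shared by at least 20 genes per pair of lists. Adjusted p-values are Benjamini-Hochberg values within each family of tests. The genes named are the 5 with the highest score per list, the 4 highest members of each enriched group per list, the 10 genes found in the most lists, and the genes of the factors themselves. The groups, tests, alternatives and this naming rule were fixed before the data were examined, except where a test is said to have been added.

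The procedures were tested on simulated data. Of lists or pairs simulated without an effect, 4.0% had p under 0.05 for location, 5.5% for folded position, 8.0% for differences of shifts, 5.0% for gene overlap, 4.0% for summit positions, 1.5% for non-coding genes, 4.5% and 3.5% for the tests of group differences and 3.0% for lengths against draws by length. For differences of shifts, all simulated groups had the same distribution, so that rate does not cover factors that differ within a form. A planted shift of 40 bp was read as 38 bp. A shift of 0.05 in folded position was found in 91.5% of 200 simulated pairs. When summits followed gene length, 13.0% of simulated lists of short genes passed Fisher's exact test and 1.5% passed with length matching.

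Alternatives were score minimums of 5 and 10, windows of 300 and 1000 bp, gene bodies with 500 bp on each side, other distances, genes of at least 2000 bp, all summits instead of the strongest, summed scores, equal numbers of top summits, a background of genes with a summit in any list, and leaving out the top 1% of scores. Differences of gene groups between factors are not reported, because a first run over all pairs of lists left few calls once lists were brought to equal numbers of top summits. A result on 1 gene family is not reported here. Lists over one form share RNAPII libraries and lists of one factor share factor libraries; the effect of this sharing could not be simulated from summit lists. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9.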

Results

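The series was designed to compare where elongation factors act along genes relative to RNAPII at different stages of transcription. S5P of the RNAPII carboxy-terminal domain is typical of early transcription and S2P of productive elongation. The 8 summit lists held 30216 summits on chromosomes 1 to 5, and the median score ranged from 3.62 for SPT5 over S2P to 6.67 for SSRP1 over S2P. A list name such as SPT5 over S2P stands for summits of SPT5 read as called against S2P; the control and which of the 4 SPT5 and 2 S2P libraries were pooled are not stated.

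SPT5 and ELF7 differed in opposite directions in how many summits they had over each RNAPII form. More summits over a form mean more places where the factor exceeded it, not that the factor prefers that form. SPT5 had 2916 summits over S5P and 298 over S2P, so that 9.27% of its summits (95% interval 8.29 to 10.3) came from the S2P list. ELF7, of the PAF1 complex, had 2687 summits over S2P and 693 over S5P, or 79.5% over S2P (78.1 to 80.8). The FACT subunits lay between them, with 56.5% of SSRP1 summits (55.5 to 57.5) and 47.1% of SPT16 summits (46.2 to 47.9) over S2P. The SPT16 share rose to 53.3% at scores of at least 5 and 72.4% at scores of at least 10, and the SPT5 share was 4.96% at scores of at least 5. List sizes also depend on the depth of the libraries, which is unknown.

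At the level of genes, the ELF7 and FACT lists over S5P were largely contained in those over S2P, whereas the SPT5 lists shared fewer genes. Of 516 genes with an ELF7 summit over S5P, 97.1% had one over S2P, and the corresponding shares were 92.2% of 3289 genes for SSRP1 and 80.8% of 4606 for SPT16. SPT5 summits lay in 223 genes over S2P and 1537 over S5P, with 65 genes in both, 29.1% of the S2P genes and 4.23% of the S5P genes. This was 5.20 times the 12.5 genes that independent lists would share. Lists of one factor are read as sharing its libraries and are not independent, so an excess is built in. Of SPT5 summits over S5P, 53.6% lay inside genes, and with 500 bp on each side of genes that list reached 2800 genes. Summits lay in 7104 of 27444 protein-coding genes in at least 1 list, in 123 genes in 7 or more lists and in 28 genes in all 8.

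GRP7 (AT2G21660), a clock-controlled glycine-rich RNA-binding protein gene on chromosome 2, was in all 8 lists and among the 5 highest scores in 5 of them. Its scores over S2P were 27.0 for SPT5 at position 9266014, 52.2 for ELF7 at 9265327, 56.4 for SSRP1 at 9265808 and 49.8 for SPT16 at 9265952. Among the 10 genes found in the most lists were also LCR69, a defensin-like gene, CP29, a chloroplast RNA-binding protein gene, KIN2, a cold-induced gene, OEP16-1, a gene for a plastid outer envelope protein, and ADS2, an acyl-lipid desaturase gene. Over S5P the highest SPT5 scores inside genes were those of AT1G79485 (24.6), OEP16-1 (18.3, 62 bp from the gene end), AT4G09620 (16.2, 22 bp from the gene end) and bHLH121 (15.5, 49 bp from the gene end), a regulator of iron homeostasis. XTH9, which encodes a cell wall xyloglucan-modifying enzyme, had the highest ELF7 score over S5P (42.5) and one of 51.4 over S2P, 583 and 592 bp from the gene end. ERF6, an ethylene response factor gene, scored 33.9 and EXL5 30.5 for ELF7 over S2P. AT2G31590 led the SPT16 lists with 53.8 over S2P and 61.5 over S5P, and EMF1, a Polycomb-associated repressor of flowering, scored 47.9 for SPT16 over S2P, 318 bp from the gene end. Of the factors' own genes, SPT16 was in 4 lists with scores from 3.0 to 9.64, while GTA2 (an SPT5 gene), ELF7 and HMG (the SSRP1 gene) were in none.

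SPT5 summits over S5P clustered at gene ends. Within 500 bp of an end lay 94.9% of them (95% interval 94.0 to 95.7), against 35.3% of random placements, a 2.69-fold excess, and the median distance was 61 bp. They fell on both sides of the end, with 50.7% inside and 44.2% outside a gene. ELF7 summits instead filled gene interiors: 98.5% over S2P and 98.3% over S5P lay inside genes, and 80.4% and 77.2% lay more than 500 bp from either end, against 32.1% and 32.0% at random. SSRP1 and SPT16 summits over S2P were inside genes in 96.1% and 94.0% of cases, most often between 300 and 400 bp from an end, where 18.1% and 14.5% of summits fell. SPT16 over S5P had a further group directly at gene ends, with 15.6% of its summits just outside genes (14.8 to 16.5) against 3.01% over S2P (2.61 to 3.45). The empirical p against random placement was 0.002 (adjusted 0.0022), the smallest that 1000 placements give, for each of these classes; the bins of 100 bp were not tested.

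**Figure D1:**
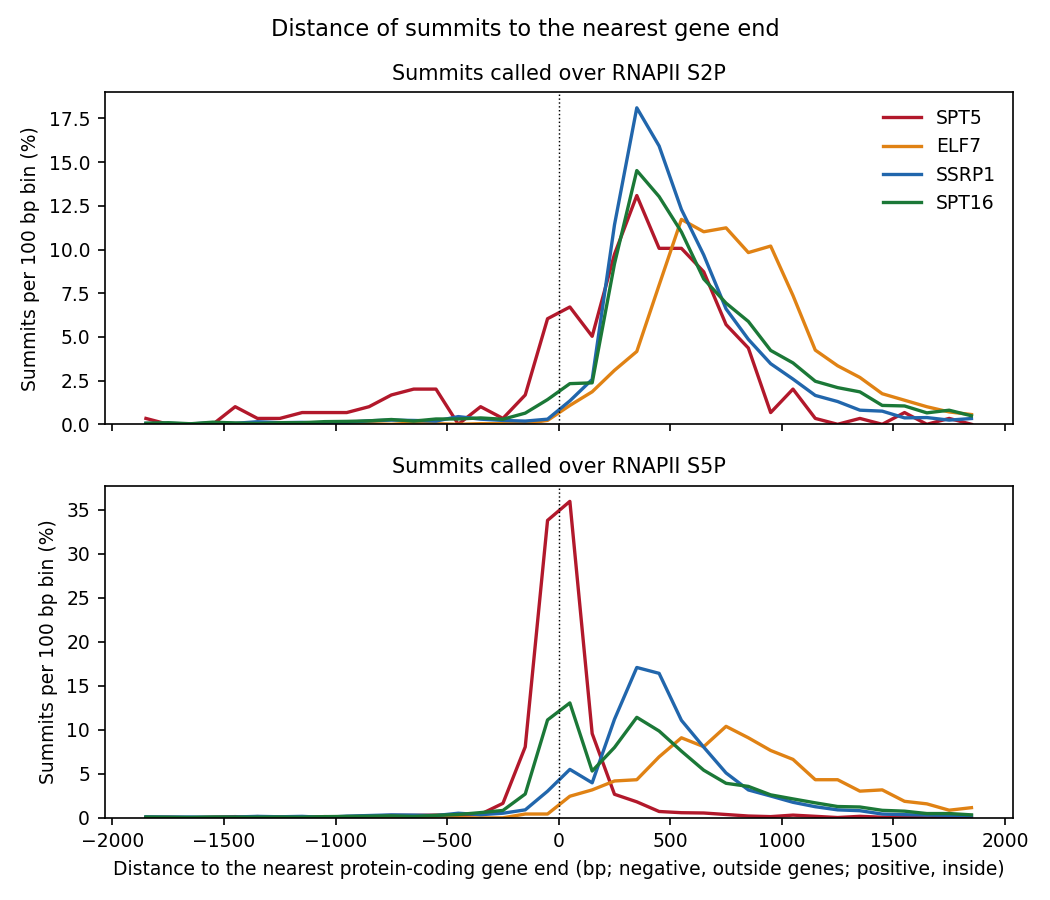
Share of summits (%) in bins of 100 bp by distance (bp) to the nearest protein-coding gene end, negative outside genes and positive inside, for the 4 factors over S2P (upper panel) and over S5P (lower panel, with its own vertical scale). Summits beyond the drawn bins are left out; SPT5 over S5P peaks at the gene end with 35.9% of summits in 1 bin, and SSRP1 over S2P peaks at 300 to 400 bp with 18.1%.

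The excess near gene ends of the FACT lists over S2P depended on the window. SSRP1 (1.44-fold) and SPT16 (1.26-fold) were above random within 500 bp but below it within 300 bp (0.705 and 0.711-fold). ELF7 was depleted within 500 bp (0.523-fold over S2P and 0.620-fold over S5P) but above random within 1000 bp (1.25 and 1.15-fold).

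Within gene bodies, SPT5, SSRP1 and SPT16 summits lay closer to a gene end over S5P than over S2P, and ELF7 summits did not differ detectably. The median folded position of SPT5 was 0.0285 over S5P (1431 genes) and 0.226 over S2P (203 genes), a difference of 0.197 (95% interval 0.177 to 0.226). The SPT16 median was 0.249 over S2P and 0.175 over S5P, a difference of 0.0737 (0.0634 to 0.0819). That of SSRP1 was 0.221 and 0.190, a difference of 0.0306 (0.0219 to 0.0383). Each of these differences had a permutation p of 1e-05 (adjusted 1.3e-05), the smallest that 100000 permutations give. The tests did not pair the lists by gene. In genes with both, the strongest summits over S2P and S5P had a median gap of 0 bp for SPT16 (3496 genes) and SSRP1 (2827 genes), and 473 bp for SPT5 (57 genes). For SPT16 and SSRP1 the differences thus do not mean that the summit moved in the typical shared gene. ELF7 stood at 0.357 over S2P and 0.346 over S5P, a difference of 0.0101 (−0.0087 to 0.0283, adjusted permutation p = 0.254).

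ELF7 lay deepest in genes of the 4 factors over both forms. Over S2P its median exceeded those of SSRP1 by 0.136 and SPT16 by 0.108, with SPT5 minus ELF7 at −0.131, and over S5P those of SSRP1 by 0.156 and SPT16 by 0.171 (adjusted permutation p = 1.3e-05 each). SPT5 over S5P lay nearer to gene ends than the other factors, with differences of −0.318 from ELF7, −0.162 from SSRP1 and −0.147 from SPT16. SPT5 over S2P did not differ detectably from SSRP1 (adjusted permutation p = 0.747) or SPT16 (0.170). With all summits instead of the strongest, the comparison of SPT5 with SPT16 over S2P passed the threshold (difference −0.0390), and that of SSRP1 with SPT16 over S5P, 0.0150 with the strongest summits, no longer did (0.0082).

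The FACT subunits SSRP1 and SPT16 had summits in largely the same genes at the same places. Over S2P they shared 4289 genes, 4.91 times the 873.6 that independent lists would share, which made up 91.5% of SSRP1 genes and 83.9% of SPT16 genes. Over S5P they shared 2876 genes, 87.4% of SSRP1 genes and 62.4% of SPT16 genes, 5.21 times the number from independent lists. In shared genes, 74.7% of SSRP1 summits over S2P lay within 250 bp of an SPT16 summit, against 28.8% for placements inside the same genes, and over S5P 78.0% against 31.5% (adjusted permutation p = 0.0021 each, from random placements). SSRP1 over S2P and SPT16 over S5P, which share no library, gave 72.1% against 30.6%. Placements were random along the gene, whereas SSRP1 and SPT16 summits over S2P favoured the same distance from gene ends. That common distance can raise these shares above random by itself. Their strongest scores correlated across genes over S2P (rho = 0.705, r = 0.714) and over S5P (rho = 0.573, r = 0.609), where shared RNAPII libraries can raise the correlation. Without a shared library the correlations were lower, at rho = 0.314 for SSRP1 over S2P with SPT16 over S5P and 0.424 for SSRP1 over S5P with SPT16 over S2P (each permutation p = 1e-05, the smallest possible; genes are not independent replicates). A positive rank correlation passed the threshold in 24 of 28 pairs of lists, and in 9 of the 12 that share no library.

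ELF7 genes were nearly all FACT genes. Of 2203 ELF7 genes over S2P, 94.8% had an SSRP1 summit and 96.2% an SPT16 summit over S2P. Of 223 SPT5 genes over S2P, 93.3% had an SSRP1 summit and 93.3% an SPT16 summit over S2P, and 82.1% an ELF7 summit. The SPT5 list over S5P overlapped less in gene bodies: 27.2% of its genes had an SSRP1 and 13.3% an ELF7 summit over S2P, while 52.8% had an SPT16 summit over S5P. All 28 pairs of lists shared more genes than independent lists would among all protein-coding genes, including the 12 pairs that share no ChIP library; for the other pairs, part of the excess can come from shared libraries. With a background of the 7104 genes in any list, a background that the lists themselves define and that lowers such odds ratios, the 6 pairs of SPT5 over S5P with the other factors turned to fewer shared genes than expected (odds ratios 0.0884 to 0.719), and the other 22 stayed above expectation.

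In genes that held both, SPT5 over S5P and FACT over S2P mostly lay on opposite sides of the gene centre. These lists differ in both factor and RNAPII form, so an effect of the factor cannot be told from one of the form. With both over S2P, SPT5 shared the side with SSRP1 in 85.3% of genes and with SPT16 in 80.6%. The strongest SPT5 summit over S5P and the strongest SSRP1 summit over S2P were on the same side of the gene centre in 41 of 403 genes (10.2%, 95% interval 7.40 to 13.5), with a median gap of 1873 bp. With SPT16 over S2P the share was 19.2% of 458 genes (15.7 to 23.1), and with ELF7 over S2P 26.4% of 197 (20.4 to 33.1). SPT16 over S5P differed: 68.9% of 758 genes (65.4 to 72.1) had both strongest summits on the same side, at a median gap of 49 bp. In shared genes, 77.5% of SPT5 summits lay within 250 bp of an SPT16 summit over S5P, against 26.1% at random. Both lists favoured gene ends, which can raise that share by itself. SSRP1 and SPT16 shared the side in 87.6% of 4003 genes over S2P (86.5 to 88.6) and 85.2% of 2696 over S5P (83.8 to 86.5). The largest adjusted p of these exact binomial tests was 3.3e-11.

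**Figure D2:**
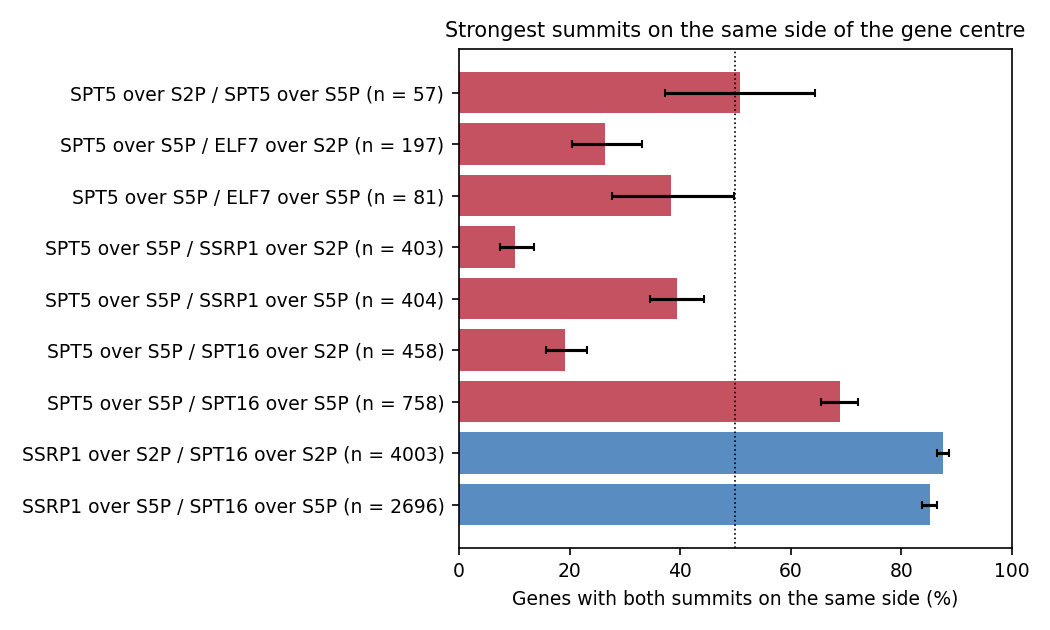
Share of genes (%) in which the strongest summits of 2 lists lay on the same side of the gene centre, with exact 95% intervals and the number of genes with both; the dotted line marks 50%. SPT5 over S5P stands at 10.2% with SSRP1 over S2P and at 68.9% with SPT16 over S5P, and the 2 FACT pairs (blue) at 87.6% and 85.2%.

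SPT5 over S5P shared the side with SSRP1 over S5P in 39.4% of 404 genes (34.6 to 44.3), a share that was 49.2% at scores of at least 5 and 60% at scores of at least 10. With ELF7 over S5P the share was 38.3% of 81 genes (27.7 to 49.7, adjusted exact p = 0.0465), and the call was lost in genes of at least 2000 bp (38.1%). SPT5 over S2P shared the side with SSRP1 over S2P in 85.3% of 190 genes (79.4 to 90.0) and with SPT16 over S2P in 80.6% of 191 (74.3 to 86.0). Its own lists over S2P and S5P shared it in 29 of 57 genes (50.9%, 37.3 to 64.4). Scores of SPT5 over S5P showed no detectable correlation across genes with SSRP1 over S2P (rho = 0.0104, adjusted permutation p = 0.834), SPT16 over S2P (0.0177, 0.730) or ELF7 over S2P (0.0658, 0.376).

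Histone genes were among the most frequently marked groups. Of 40 genes for core and linker histones, 34 (85.0%, 95% interval 70.2 to 94.3) had an SSRP1 summit over S2P, 33 an SPT16 summit and 28 an ELF7 summit, against 17.1%, 18.6% and 8.03% of all protein-coding genes (odds ratios 27.7, 20.7 and 27.1; adjusted Fisher's exact p = 5.0e-19, 7.4e-17 and 4.1e-20). SPT5 had summits in 3 histone genes over S2P (odds ratio 10.0, adjusted exact p = 0.0101; not called with 500 bp on each side, odds ratio 5.83) and in 0 over S5P. The H4 gene HIS4 scored 19.3 for SSRP1, 19.9 for SPT16 and 13.2 for ELF7 over S2P, and the H2A genes HTA13 and HTA6 scored 13.4 and 12.1 for SPT16 over S2P. Histone genes are short, with a median of 963.5 bp, and length-matched lists reached 12.9%, 13.4% and 5.71% for the same 3 lists.

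Rapid stress response genes, such as those of jasmonate and ethylene signalling, were enriched in 7 of the 8 lists. SPT16 summits over S2P lay in 41 of 54 (75.9%, 95% interval 62.4 to 86.5), SSRP1 summits in 36 and ELF7 summits in 30 (odds ratios 13.9, 9.77 and 14.5; adjusted Fisher's exact p = 3.0e-18, 1.4e-14 and 6.1e-18). The members with the highest ELF7 scores over S2P were ERF6 (33.9), AT5G51190 (21.9), the ethylene response factor gene ERF2 (21.8) and WRKY22 (14.5), a defence transcription factor gene. SSRP1 over S2P scored 27.0 at the jasmonate biosynthesis gene AOS, and SPT16 over S2P 21.3 at the cold regulator gene CBF2 and 22.7 at the calmodulin-like gene CML38. Cold and abscisic acid response genes had summits in 13 of 25 cases for SSRP1 over S2P (odds ratio 5.27, adjusted exact p = 2.6e-04), led by KIN2 (31.8) and followed by the dehydration-induced gene ERD7 (14.4).

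**Figure D3:**
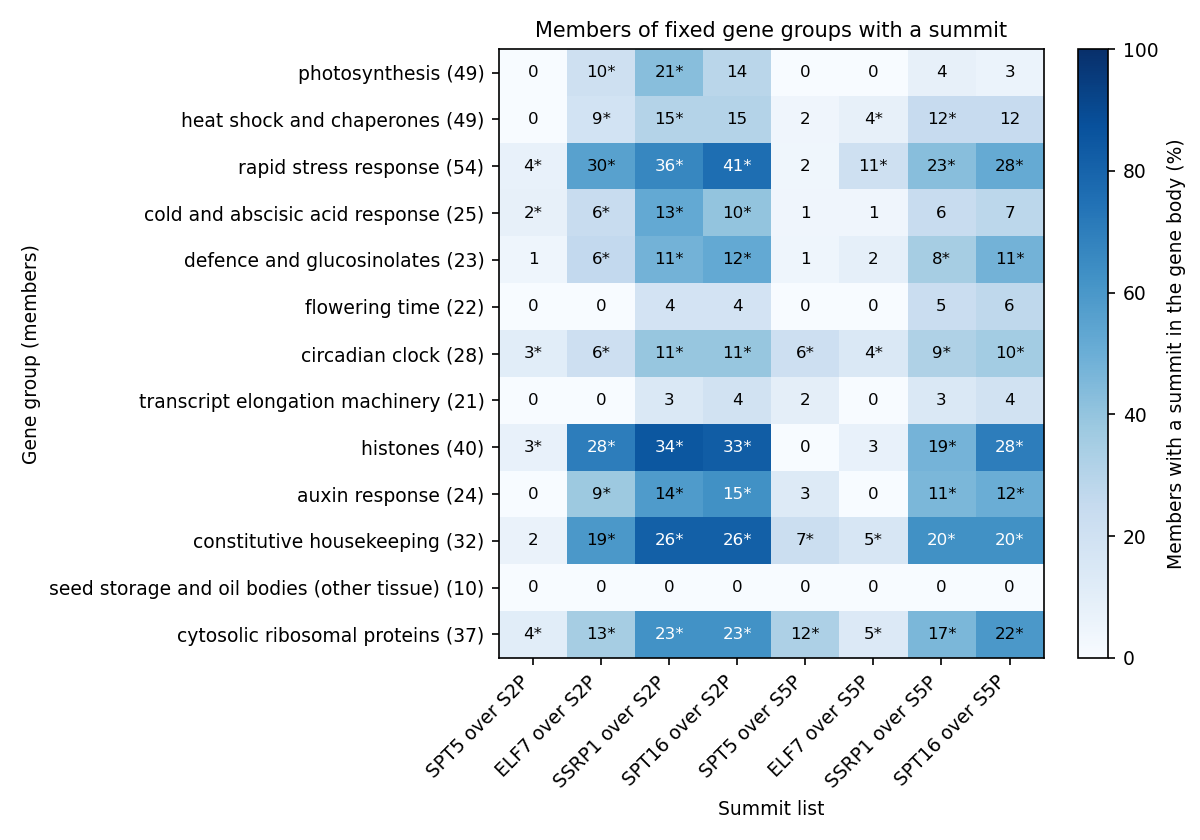
Members of each gene group with a summit in the gene body, by list; numbers are members, group sizes stand in parentheses, the colour is the share of members (%), and an asterisk marks an adjusted Fisher's exact p under 0.05. Histone, housekeeping and rapid stress response genes reach 34, 26 and 36 members for SSRP1 over S2P. The 10 seed storage genes have 0 in all 8 lists, which is too few members to call a depletion.

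Genes of constitutive cell functions were marked by FACT over both forms. Housekeeping genes, which include tubulin, actin and ubiquitin genes, had SSRP1 summits over S2P in 26 of 32 cases (81.2%, 95% interval 63.6 to 92.8) and SPT16 summits in 26, and both had 20 over S5P. The tubulin gene TUB8 scored 27.6, UBQ3 14.8 and ACT7 14.8 for SPT16 over S2P. Cytosolic ribosomal protein genes were only those found by name, so the group need not cover the whole family. They had SSRP1 and SPT16 summits over S2P in 23 of 37 cases each (62.2%, 44.8 to 77.5). They also had the highest odds ratio of the 13 groups for SPT5 over S5P, with 12 members (32.4%, 18.0 to 49.8; odds ratio 8.15, adjusted exact p = 2.3e-06), among them RPS13A at 13 bp, RPSAb at 10 bp and RPS6 at 16 bp from a gene end.

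Auxin response genes had SPT16 summits over S2P in 15 of 24 cases and SSRP1 summits in 14 (odds ratios 7.30 and 6.81; adjusted exact p = 1.2e-05 and 2.7e-05), with IAA7, an auxin-responsive repressor gene, at scores of 23.4 and 21.7. Circadian clock genes were enriched in all 8 lists, with 11 of 28 for each FACT subunit over S2P and 6 for SPT5 over S5P, where FKF1, a blue-light receptor gene, scored 12.2 and GI 6.28. With length matching the clock call was lost for ELF7 over S2P (adjusted permutation p = 0.102 from random lists) and for SPT16 over S2P (0.0728) and S5P (0.109), and with 500 bp on each side of genes for SPT5 over S5P (odds ratio 2.40) and SPT16 over S5P (2.31). In GI the SPT5 summit over S5P lay 41 bp from a gene end and the SPT16 summit over S5P 96 bp. Defence and glucosinolate genes had SPT16 summits over S2P in 12 of 23 cases (odds ratio 4.77, adjusted exact p = 9.9e-04), among them the immune regulator gene PAD4 (16.8) and MAM1 (15.8), of glucosinolate biosynthesis.

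Photosynthesis genes were enriched for SSRP1 over S2P, with 21 of 49 (42.9%, 95% interval 28.8 to 57.8; odds ratio 3.65, adjusted exact p = 8.7e-05), including NPQ4 (13.8), the photoprotection gene for PsbS, and the plastocyanin gene PETE1 (10.1), and for ELF7 over S2P, with 10 (odds ratio 2.95, adjusted exact p = 0.0114). These ratios turned below 1 for ELF7 at scores of at least 5 (0.559) and for SSRP1 at scores of at least 10 (0.725), and the ELF7 call was lost with 500 bp on each side of genes (1.90). Heat shock and chaperone genes were enriched for SSRP1 over S2P (15 of 49, odds ratio 2.15, adjusted exact p = 0.0386) and over S5P (12), and for ELF7 over both forms, but none of these held with length matching (adjusted p = 0.0739 to 0.103). The Hsp90 gene HSP81-3 scored 23.3 for SSRP1 and the heat regulator gene DREB2A 18.5 for SPT16 over S2P. Flowering time genes and genes of the elongation machinery passed in no list by gene bodies, with at most 6 of 22 and 4 of 21 members. With 500 bp on each side both were called for SPT5 over S5P (odds ratios 3.31 and 3.53, adjusted exact p = 0.0398 and 0.0350). Seed storage and oil body genes, a control from another tissue, had summits in 0 of 10 in any list. With so few members the upper 95% limit was 30.8%, and no list was called depleted (lowest adjusted exact p = 0.330, SPT16 over S2P). These zeros are thus a weak control.

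Of 104 tests of gene groups, 56 were enriched and 0 depleted, and 46 were enriched with length matching. Against the genes with a summit in any list, 12 enrichments held: histones, housekeeping and rapid stress response for ELF7, photosynthesis, histones, housekeeping and cold response for SSRP1, and histones, housekeeping and rapid stress response for SPT16, all over S2P, with rapid stress response for ELF7 and housekeeping for SSRP1 over S5P. In 4 other tests, histones, photosynthesis and rapid stress response for SPT5 over S5P and photosynthesis for SPT16 over S5P, fewer members than expected had summits against that background.

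Photosynthesis genes with FACT summits over S2P seldom had them over S5P, in tests added after the data were seen. Of 21 members with an SSRP1 summit over S2P, 3 had one over S5P (14.3%), against 64.9% of the other genes in that S2P list (adjusted Fisher's exact p = 1.4e-04). For SPT16 these were 3 of 14 (21.4%) against 72.9% (0.0024). With fewer members left, the differences kept their direction but did not pass at scores of at least 5 (−47.3 percentage points for SSRP1 and −29.1 for SPT16). With the same number of top summits, that of SSRP1 did not pass over all 52 comparisons, with 3 of 9 members (33.3%, 95% interval 7.49 to 70.1) against 71.8% (exact p = 0.0187, adjusted 0.324). Histone genes found in only 1 list were in the S2P list in 25 of 25 cases for ELF7 and 15 of 15 for SSRP1, but other genes found in 1 list were there in 99.1% and 86.4% of cases (adjusted exact p = 1 each). Rapid stress response genes stood 16 against 3 for SSRP1 (84.2%, other genes 86.6%) and 14 against 1 for SPT16 (93.3%, other genes 60.9%; adjusted exact p = 0.176). Of 52 comparisons each, 2 passed among genes of the S2P lists and 1 among genes found in 1 list. The latter came from 3 histone genes for SPT5 (adjusted exact p = 0.0466) and was lost under every alternative that left members to test.

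Genes with summits were longer than genes without in 7 lists, but shorter than summits placed by gene length alone would give. The median gene with an SPT5 summit over S5P had 2536 bp, 485 bp more than genes without one (95% interval 414 to 564), and the differences were 350.5 bp for SPT16 over S5P, 309.5 bp for ELF7 over S5P and 203 bp for SSRP1 over S2P (adjusted permutation p = 1.1e-05 each). Genes with SPT5 over S2P differed by −13 bp (−223 to 129, adjusted permutation p = 0.880). A longer gene holds more summits by chance: as many genes drawn in proportion to length had medians of 2878 bp for SPT5 over S5P and 2794 to 2908 bp for the other lists, above the observed 2536 bp and 2065 to 2381.5 bp (adjusted permutation p = 0.0020 from these draws in all 8 lists, the smallest possible; a test added after the data were seen). At scores of at least 10, 3 lists kept a difference, and ELF7 over S2P and over S5P turned to −31 and −13 bp.

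Small nucleolar RNA (snoRNA) genes, whose products guide the modification of ribosomal RNA, were enriched in 7 lists, with the highest fold for SPT5 over S2P. Of its 298 summits, 30 (10.1%, 95% interval 6.90 to 14.1) lay within 250 bp of a snoRNA gene, 97.4 times the random share. The folds were 14.2 and 17.3 for SSRP1 over S2P and S5P, 11.1 and 9.65 for SPT16, 12.3 for SPT5 over S5P and 4.99 for ELF7 over S2P. Each had a permutation p of 0.002 (adjusted 0.0046), the smallest that 1000 random placements give. By number, the longer FACT lists had more such summits, with 72 and 69 for SSRP1 and 69 and 68 for SPT16, and SPT5 over S5P had 35. Of these, 51, 50, 52, 48 and 26 lay outside protein-coding genes, but only 4 of the 13 for ELF7 over S2P. Neighbouring genes were tested for SPT5 over S2P only. The SPT5 summits over S2P outside protein-coding genes with the highest scores at snoRNA genes were on chromosome 1 at 8756404 (AT1G05907 and AT1G05917, score 8.68) and on chromosome 3 at 7682539 (AT3G21805, AT3G04155 and AT3G04165, 6.62), 9550759 (AT3G04985, 6.60) and 8979237 (AT3G24612 and AT3G24614, 5.39), chosen after the values were seen.

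**Figure D4:**
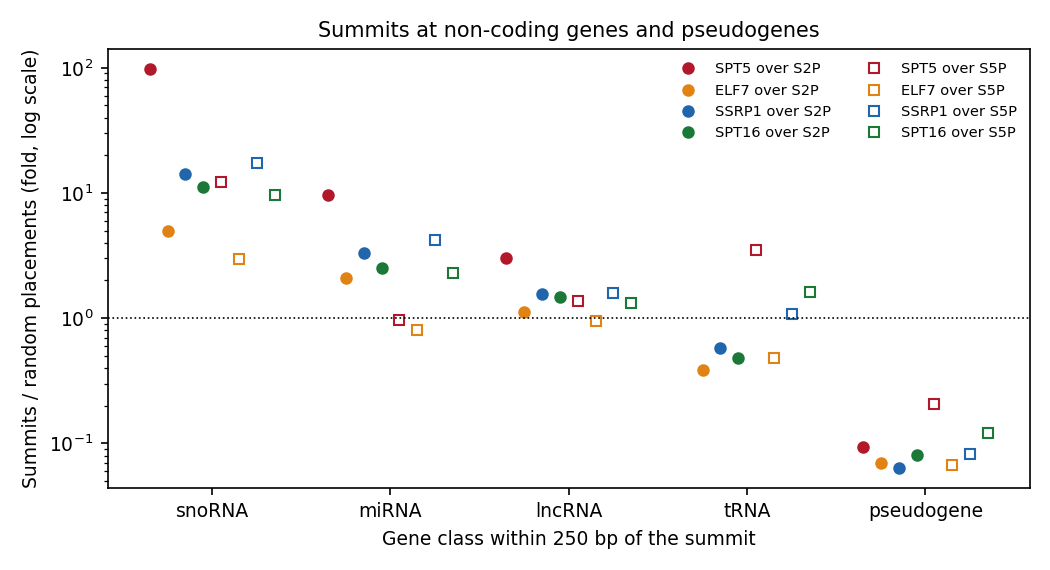
Summits within 250 bp of non-coding genes and pseudogenes relative to random placements (fold, log scale), with filled circles for lists over S2P and open squares for lists over S5P; lists with 0 summits at a class are not drawn. SPT5 over S2P stands highest at snoRNA genes (97.4), SPT5 over S5P at tRNA genes (3.47), and all lists lie below 1 at pseudogenes.

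Transfer RNA genes, which RNA polymerase III transcribes, were enriched for SPT5 over S5P (29 summits, 3.47-fold) and SPT16 over S5P (34 summits, 1.61-fold). They were depleted for SPT16 over S2P (9 summits, 0.479-fold, adjusted permutation p = 0.0387 from random placements). The 2 enriched lists also exceeded random placements within 500 bp of protein-coding gene ends, by 2.69-fold for SPT5 and 1.79-fold for SPT16. Neighbouring protein-coding genes were not set apart for transfer RNA genes, so whether the excess is particular to them was not tested. MicroRNA genes were enriched for SPT5 over S2P (5 summits, 9.69-fold) and both FACT subunits over both forms (2.31 to 4.19-fold). Antisense RNA genes were enriched in the 4 FACT lists (2.77 to 4.1-fold). The 4843 genes that the gene table classes as pseudogenes were depleted in all 8 lists (0.0637 to 0.205-fold). The gene table has no class for transposable element genes, and whether the pseudogene class holds any was not examined. MicroRNA, antisense RNA, long non-coding RNA and pseudogene classes were added after the data were seen. Of 32 tests of these added classes 15 were above random, and of 32 tests of the planned classes 9 were.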

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

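The tests of differences between shifts and of the S5P control were chosen only after positions had been seen; the test of weak calls was set before its result. The test of the control as the only cause replaced an earlier one, on SSRP1 alone, whose outcome changed at stricter scores. The shift of the median folded position from S2P to S5P differed between factors in 5 of 6 pairs. The SPT5 median moved towards gene ends more than that of ELF7, by −0.187 (95% interval −0.222 to −0.158). It also moved more than that of SSRP1, by −0.167 (−0.197 to −0.143), and that of SPT16, by −0.124 (−0.154 to −0.101). The SPT16 median moved towards gene ends more than that of ELF7, with ELF7 minus SPT16 at 0.0636 (0.0430 to 0.0842). It also moved more than that of SSRP1, with SSRP1 minus SPT16 at 0.0431 (0.0308 to 0.0551). Each had an adjusted permutation p of 0.0001, the smallest that 10000 permutations give. The error rate of this test was simulated only for factors that do not differ within a form. ELF7 minus SSRP1, at 0.0204 (−0.0001 to 0.0411, adjusted permutation p = 0.0540), was borderline: it passed with another random seed, before the interval was required to exclude 0, and under some alternatives.

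The strongest of these shifts reflects SPT5 summits over S5P at gene ends. Weak calls alone are argued against, since 94.6% (87.9 to 98.2) of the 93 summits with scores of at least 10 lay within 500 bp of an end, against 34.9% at random. If the S5P control alone set the place of every summit, the other lists over S5P would stand near ends as often. The highest of them, SPT16, reached 63.4% (62.3 to 64.5). That share also falls with summits in gene interiors, of which SPT16 had 2503 and SPT5 83. By number, SPT16 had 4689 summits near an end and SPT5 2767. The lower share thus cannot tell whether the control placed the SPT5 summits at ends. An effect of the control, whole or partial, which may expose other signal where S5P is low, stays open. SPT16 over S5P lay on the same side of the gene centre as SPT5 in 68.9% of shared genes. SSRP1 over S5P did so in 39.4%, or 49.2% at scores of at least 5. Yet 42.4% of SPT5 summits in shared genes lay within 250 bp of an SSRP1 summit over S5P, against 26.7% at random. Common closeness to gene ends can raise that share. The SSRP1 values thus point both ways. Over S2P, SPT5 shared the side with SSRP1 in 85.3% of genes and with SPT16 in 80.6%. The SPT5 lists over S2P and S5P shared it with each other in 50.9%. A biological difference, with SPT5 and part of FACT at gene ends where S5P is low, is a hypothesis that these lists without signal tracks or strand do not decide.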

How the results depend on the processing

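No paired analysis was possible because the lists carry no replicate columns; for the same reason no library could be left out, and the top 1% of scores was left out instead. The lists hold chromosomes 1 to 5 only, so that adding organelle sequences would add no summits and was not run. Of 2057 values under 17 alternatives, 1848 were labelled as unchanged. For a called test this meant that call and direction were kept. Tests called neither at first nor under the alternative counted as unchanged whatever their direction. Counts of calls and shares of summits were judged by size alone. A further 163 had no summit or member left and are not counted, a rule set after results were seen. Alternatives for sides of the gene centre, group differences and differences of shifts were also added after the data were seen. Where no cause is named below, the cause was not tested. Unknown depth limits the comparison of list sizes.

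At scores of at least 5 and 10, 15508 and 4522 summits were left. The share over S2P became 4.96% and 6.06% for SPT5, 83.6% and 87.8% for ELF7, 64.2% and 79.2% for SSRP1, and 53.3% and 72.4% for SPT16. At scores of at least 10, where fewer summits were tested, calls were lost for SPT5 over S2P near gene ends (1.87-fold) and inside genes (1.58) and for ELF7 over S5P near ends (0.689); enriched groups fell from 56 to 20, non-coding enrichments from 24 to 10 and lists with longer genes from 7 to 3. Length differences were then 435 bp for SPT5 over S5P and 74 bp for SSRP1 over S2P, not called, and −31 and −13 bp for ELF7 over S2P and S5P; at scores of at least 5, ELF7 over S2P had 65.5 bp, not called. Odds ratios of photosynthesis genes reversed, to 0.559 for ELF7 over S2P at scores of at least 5 and 0.725 for SSRP1 over S2P at scores of at least 10.

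Near gene ends, SSRP1 and SPT16 over S2P reversed with 300 bp (0.705 and 0.711), as their summits mostly lie deeper, and ELF7 with 1000 bp (1.25 and 1.15). SPT5 over S5P fell below random inside genes without summits in several genes (0.944) and at scores of at least 5 (0.890). With all summits, SPT5 minus SPT16 over S2P was called (−0.0390) and SSRP1 minus SPT16 over S5P was not (0.0082). The ELF7 minus SSRP1 shift was called with all summits (0.0274), longer genes (0.0251) and without the top 1% (0.0240).

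SPT5 and ELF7 over S5P lost their call for opposite sides with flanks (42.4%), in longer genes (38.1%) and at scores of at least 5 (39.1%). SPT5 and SSRP1 over S5P lost it at scores of at least 5 (49.2%) and reversed, uncalled, at 10 (60%), where SPT5 over S5P and SPT16 over S2P also lost it (30%). Against genes with a summit in any list, odds ratios of SPT5 over S5P reversed to 0.273 and 0.719 for ELF7 over S2P and S5P, 0.113 and 0.361 for SSRP1, and 0.0884 and 0.523 for SPT16, and 12 group enrichments were left; this background leaves out genes in no list, which lowers odds ratios. With distances of 50 bp, SPT5 over S5P near SPT16 over S2P turned to 1.21-fold and the converse to 1.37-fold, with 1.05-fold at 100 bp, none called. With 500 bp flanks, flowering time genes were called in SPT5 over S5P (odds ratio 3.31, from 0 members). Group differences among genes of the S2P lists fell from 2 to 0 at both score minimums. Those among genes found in 1 list went from 1 to 0 at both score minimums, with the same number of top summits and without the top 1%, and to 2 with flanks.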

Other observations

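All tests in this part were chosen after results were seen, except those of snoRNA genes away from protein-coding genes and of weak calls over S2P; the tests of short RNA genes and of photosynthesis genes replaced earlier ones, the latter a sign test that also covered histones and took an even split as its expectation. Gene families sharing a symbol stem were tested beside the fixed lists, with some members in common. KCS genes, which encode enzymes of very-long-chain fatty acid synthesis for the cuticle, had ELF7 summits over S2P in 11 of 21 cases (52.4%, 95% interval 29.8 to 74.3; odds ratio 12.7, adjusted Fisher's exact p = 2.5e-04) and SSRP1 and SPT16 summits in 12 each. SAUR genes, which are rapidly induced by auxin, had SSRP1 summits over S2P in 12 of 16 cases (odds ratio 14.6, adjusted exact p = 4.9e-04), ELF7 summits in 8 and SPT16 summits in 10. FLA genes, which encode cell wall arabinogalactan proteins, had ELF7 summits over S2P in 8 of 19 cases (odds ratio 8.36, adjusted exact p = 0.0046) and SSRP1 and SPT16 summits in 10 each.

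Tubulin TUB genes, some of them also in the housekeeping group, had SSRP1 and SPT16 summits over S2P in 8 of 9 cases each (adjusted exact p = 0.0024 and 0.0025). Homeobox HB genes had them in 17 and 18 of 37 (adjusted exact p = 0.0042 and 0.0036). Over 220 families and 1760 tests, 94 were enriched, 55 of them also with length matching, and 7 were depleted.

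The snoRNA signal of SPT5 over S2P is the second pattern weighed. Spill-over from neighbouring protein-coding genes is argued against, since at the 176 snoRNA genes more than 250 bp from such genes the fold over random was 149.7 (25 summits, permutation p = 0.002 from random placements, the smallest possible), and 26 of the 30 summits lay outside protein-coding genes. A few loci are argued against by 28 separate places at least 10000 bp apart. A signal of the same strength at all short RNA genes is argued against, since the highest upper limit of the fold at transfer, small nuclear and microRNA genes stayed under the lower limit at snoRNA genes, with 43.9 against 66.7 for SPT5 over S2P, 5.11 against 8.60 for SPT5 over S5P, 4.69 against 11.1 for SSRP1 over S2P and 3.61 against 8.62 for SPT16 over S2P; a weaker signal shared by RNA genes stays open, with microRNA folds over S2P of 9.69 for SPT5, 3.33 for SSRP1 and 2.52 for SPT16. Whether the RNAPII control shapes this signal was not tested. The SSRP1 and SPT16 lists were enriched at snoRNA genes too, and SPT5 had 35 such summits over S5P. SPT5 acting with RNAPII at independently transcribed snoRNA genes is a candidate explanation that was not tested further.

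The third pattern is that photosynthesis genes of the S2P list were seldom in the S5P list for SSRP1 (3 of 21) and SPT16 (3 of 14). Lists of unequal length could not be tested as a cause for SPT16. Its S5P list was the longer, with 7394 summits against 6578 over S2P, so the same number of top summits only shortened it. Members in both lists could then only fall, and fell from 3 to 1 (adjusted exact p = 2.5e-04). For SSRP1, list length cannot be told apart (adjusted exact p = 0.324). The share went from 14.3% (95% interval 3.05 to 36.3) against 64.9% of other genes to 33.3% (7.49 to 70.1) of the 9 members left, against 71.8% (unadjusted exact p = 0.0187). The call was thus lost with fewer members and a smaller gap, which does not by itself support list length as the cause. Gene length is argued against for both, whose members were in the S5P list less often than length-matched genes of the S2P list (permutation p from random draws = 2.0e-04 for SSRP1, the smallest possible, and 4.0e-04 for SPT16), as are weak calls over S2P as the only cause, by genes matched on their S2P score (0.0012 and 0.0140), although neither difference passed at scores of at least 5 (−47.3 and −29.1 percentage points). For SPT16 there was no detectable surplus over S2P (14 of 49, odds ratio 1.75, adjusted exact p = 0.160), and the pattern rests on few members over S5P (3 of 49, odds ratio 0.323, adjusted exact p = 0.0920; 0.271 and 0.0360 with 500 bp on each side of genes). Less SPT16 relative to S5P at these genes is a biological hypothesis, and for SSRP1 the pattern stays open.

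A related hypothesis was that genes found only over S2P are shorter than genes found only over S5P. The medians were 2029 against 2552 bp for SPT5 (adjusted permutation p = 1.6e-04) and 2084 against 2396 bp for SPT16 (4.0e-05), in the direction of the hypothesis. For SSRP1, with 2123 against 2299 bp (0.0748), and for ELF7, with 2158.5 against 2576 bp and 15 genes found only over S5P (0.180), the test did not pass and the hypothesis stays open.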
